A study of Mus musculus with 6 samples.

How the data were processed

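Polyadenylated RNA from the ventral lumbar cord of 6 SOD1G93A mice (3 given AAV-GFP, 3 given AAV-NDNF) was made into libraries and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The submitters' processing notes name cutadapt, HISAT2, HTSeq and DESeq2 and the mouse build mm10; versions, the gene annotation and strand settings were not given in the sources used here. Groups and replicate numbers were taken from the sample titles and treatments in the labels.

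The deposited table holds 28162 genes. Per the file headers and values, its per-sample columns are a normalized signal, namely gene read counts that the authors divided by one size factor per library. Each value was a whole multiple of the value of 1 read in its library (100% of values, tolerance 0.001), so whole reads could be recovered. The recovered reads came to between 15335789 and 20060987 per library, and mitochondrially encoded genes took 5.28% to 7.94% of them. Per the file headers, the authors also deposited log2 fold changes with their standard errors, the Wald score and p-values with adjusted p-values from DESeq2, of which 20315 genes have an adjusted p.

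The test planned before the data were examined was edgeR's quasi-likelihood test on raw counts. Since the deposited values are normalized, the main test became limma with a mean-variance trend and robust variances on log2(normalized count + 1), for genes with at least 10 normalized counts in at least 3 libraries (17480 genes). The edgeR test on recovered reads was kept as an added alternative. Both are two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The pseudocount of 1 makes fold changes of low genes smaller than the ratio of their values. Gene lists were tested with camera (limma, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over lists with at least 5 tested members. Of 39 lists fixed before the data were examined, 36 were tested, the blood and skeletal muscle lists had too few members, and the sex-linked list served as a check. Called lists were tested again with a correlation estimated from the residuals and with fry. The preset is far below the estimated correlation of some lists, such as 0.74 for interferon response and 0.91 for nuclear oxidative phosphorylation.

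Genes named in the text were chosen by a rule fixed before the data were examined. It takes Ndnf, Sod1 and 8 marker genes with any value, up to 8 called genes per direction or, where fewer than 5 qualify, the 5 with the smallest p, and up to 4 members with the smallest p of each list past the threshold. Genes named outside that rule are said to be. Some genes that the rule or the tables would bring up are not reported here. Gene coordinates come from GENCODE M21 (mm10), which held 27638 of the 28162 symbols (98.1%).

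No pair of libraries agreed within counting noise. The first 3 principal components of the log2 values held 32.2%, 23.3% and 18.5% of the variance; AAV-GFP replicate 2 and AAV-NDNF replicate 3 lay at the ends of the first (40.3 and −52.0) and neither of the first 2 separated the groups, which the third did narrowly (−22.7 to −11.7 in controls, −10.9 to 35.5 after AAV-NDNF). No sequencing batch or date was given in the sources used here. Alternatives covered scaling (upper quartile, TMM), the filter on low values, the pseudocount, the tool (DESeq2, limma-voom with quality weights, edgeR in 2 forms), a replicate block, a dorsal horn covariate, a rule of unadjusted p with a fold limit, and leaving out libraries.

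The scripts were tested on simulated counts drawn from the means and sizes of these libraries for 17480 genes. Each gene was drawn independently around a pooled mean, without the structure between libraries seen in the principal components. Recovery in the real data can therefore be lower. In the AAV-NDNF against AAV-GFP simulation limma recovered 16% of 50 genes changed by 0.5 on the log2 scale, 74% of those changed by 1, 90% by 2 and 96% by 4, with 12 false calls among 150. DESeq2 made 22 false calls among 167. Camera called 5 of 5 lists shifted by 0.3 and 0 others, with members drawn independently. The software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and, for plots, matplotlib 3.10.9.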

Results

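The ventral part of the lumbar spinal cord was profiled by polyadenylated RNA sequencing in SOD1G93A mice, which carry a mutant superoxide dismutase 1 transgene and are a standard model of amyotrophic lateral sclerosis. The animals had received an adeno-associated virus (AAV) into the intrathecal space on postnatal day 74, and tissue was taken on day 104. The virus carried either NDNF (neuron-derived neurotrophic factor, a secreted glycoprotein) or green fluorescent protein (GFP) as the control. Each group held 3 libraries, described as biological replicates. The reads assigned to genes came to 18839634, 17424788 and 15844157 in AAV-GFP libraries 1 to 3 and to 20060987, 15335789 and 15942771 in AAV-NDNF libraries 1 to 3. All 6 libraries had reads of Y-linked genes and at most 3.9 normalized counts of Xist, the pattern of male tissue. Below, values are normalized read counts, a log2 fold change is AAV-NDNF minus AAV-GFP on the log2(value + 1) scale, and ± is the SD over n = 3 libraries unless named a standard error (SE).

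The delivered gene was examined first, since it checks the group labels. Ndnf (chromosome 6, 65671590 to 65712326 on the plus strand, mm10) stood at 171.4, 128.0 and 158.1 in the AAV-GFP libraries and at 5286, 7077.1 and 673.7 in the AAV-NDNF libraries. The group means differed 28.5-fold, and the lowest AAV-NDNF library was 3.93-fold above the highest control. Within the AAV-NDNF group the level spanned a 10.5-fold range, with replicate 3 lowest. The log2 fold change was 4.27 (SE 0.85), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. In limma over all genes it did not pass (Benjamini-Hochberg adjusted p = 0.53), whereas without AAV-NDNF replicate 3 it did (log2 fold change 5.33, adjusted p = 9.59e-09). The authors' deposited table gives a log2 fold change of 4.83 with a DESeq2 adjusted p of 8.92e-05. The species and extent of the delivered sequence were not given in the sources used here, so these counts hold endogenous transcripts and whatever part of the vector transcript matches the mouse gene. Sod1, whose mouse copy lies on chromosome 16 and whose reads can include those of the human transgene, was 2055 ± 251 in controls and 2143 ± 611 after AAV-NDNF. That difference of 0.03 on the log2 scale was smaller than the spread between libraries.

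**Figure D1:**
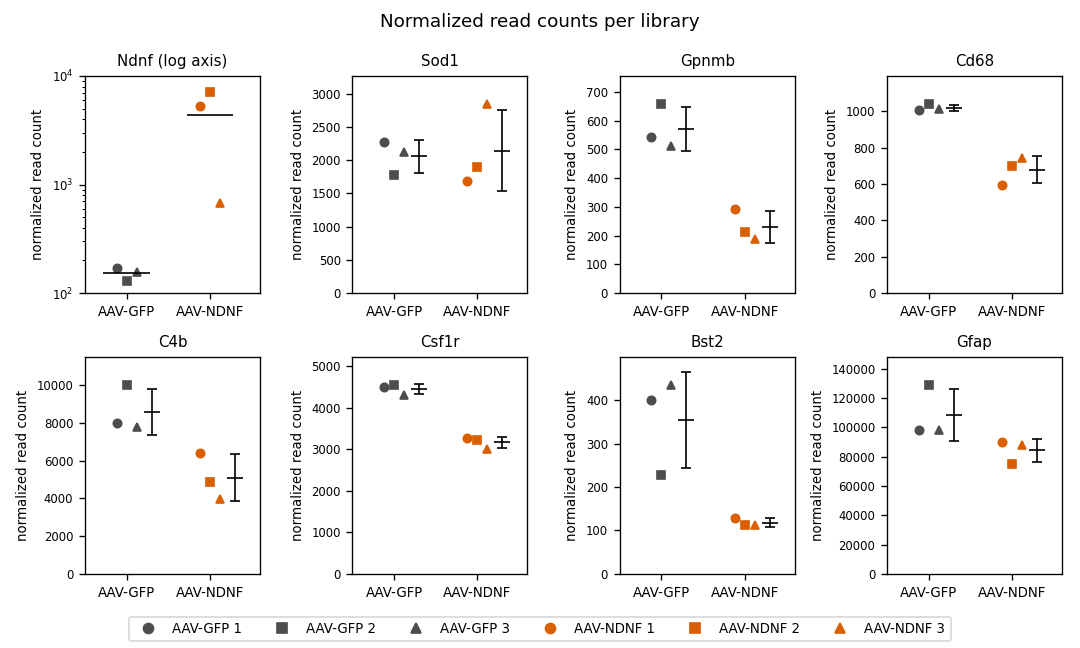
Normalized read counts per library (y axis; logarithmic for Ndnf, linear from 0 for the others) in the AAV-GFP and AAV-NDNF groups. Symbols are single libraries, and black marks are the group mean with SD bars (mean alone for Ndnf); for Gpnmb, Cd68, C4b, Csf1r and Bst2 each AAV-NDNF library lies below each control, while Sod1 overlaps.

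The main question was which transcripts differed in the ventral cord 30 days after gene delivery. The genes with the smallest p-values among those lower after AAV-NDNF included phagocyte genes and an interferon-induced gene. Gpnmb, a transmembrane glycoprotein of phagocytes, was 571 ± 76.1 in controls and 230.9 ± 55.6 after AAV-NDNF (log2 fold change −1.32, SE 0.18). Bst2 (tetherin), an interferon-induced membrane protein, was 354.4 ± 111 against 118 ± 10.03 (−1.53). Lgals3bp, a secreted galectin-binding protein, was 1910 ± 485 against 841.1 ± 21.2 (−1.15). Mpeg1 (perforin-2), a pore-forming protein of macrophages, was 4157 ± 357 against 2568 ± 69.8 (−0.69), and Mertk, a phagocytic receptor kinase, was 718.7 ± 59.8 against 407 ± 57.7 (−0.83). In the other direction Ide, the insulin-degrading enzyme, was 1141 ± 96.3 in controls and 1770 ± 47.0 after AAV-NDNF (0.64). Dbp, a clock-controlled transcription factor, was 1062 ± 47.9 against 1423 ± 104 (0.42). Cdhr3, a cadherin of ciliated cells, was 6.83 ± 2.54 against 31.1 ± 11.1. Fam177a2 was 4.95 ± 2.11 against 25.1 ± 3.80, an uncertain value because a near-identical copy, Fam177a, can share its reads.

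None of these differences passed limma over all 17480 genes tested. The smallest adjusted p was 0.214, shared by Gpnmb, Bst2, Lgals3bp and Mpeg1, and 818 genes had an unadjusted p under 0.05, 617 of them lower and 201 higher. That count was 544 without AAV-GFP replicate 1 and 1535 without AAV-NDNF replicate 1. The edgeR quasi-likelihood test on the recovered reads called 0 genes as well (smallest adjusted p 0.137), with 842 at an unadjusted p under 0.05. Neither 818 nor 842 exceeds the share of 0.05 of tested genes that chance alone gives. The authors' deposited table, from DESeq2, lists 54 genes with an adjusted p under 0.05, of which 50 are lower and 4 higher. The latter are Ndnf, Ide, Glo1-ps and Gm49066, named here after their values were seen. Of those 54 genes, 52 were tested in limma, and all 52 had an unadjusted p under 0.05 there. Without AAV-GFP replicate 2, limma called 43 genes, all lower, and without AAV-NDNF replicate 3 it called 11. Many of those 43 were interferon-induced genes such as Bst2. AAV-GFP replicate 2 was the control whose interferon response score (−1.02) lay among the AAV-NDNF libraries, so its omission favours such calls. The 2 groups did not overlap at 1705 genes (9.8%), where chance gives 10%.

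Microglial genes were lower as a group. The list of disease-associated microglia, the phagocytic state that microglia take on around neurodegeneration, fell to a mean of 0.689 times the control level (mean log2 fold change −0.54). All 20 tested members had fold changes below 0, and 13 of them fell when adjusted over the list alone, against 0 over all genes tested. Cd68, a lysosomal glycoprotein of phagocytes, was 1019 ± 17.2 in controls and 679.3 ± 76.3 after AAV-NDNF. Itgax, an integrin induced in this state, was 428.1 ± 58.6 against 238.8 ± 64.3, and Ctsd (cathepsin D) was 9933 ± 211 against 6698 ± 1508. Trem2, the lipid-sensing receptor needed to enter this state, was 1081 ± 54.1 against 796.7 ± 174 (−0.46). The list passed camera with a preset correlation (adjusted p = 3.03e-22), but not with an estimated one (adjusted p = 0.184 with an estimated correlation).

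Genes of resting microglia differed less. The homeostatic microglia list fell to 0.825 times the control level, with all 14 members below 0 and 5 of them past the threshold when adjusted over the list alone. Csf1r, the receptor on which microglia depend for survival, was 4450 ± 120 in controls and 3170 ± 137 after AAV-NDNF. Cx3cr1, the fractalkine receptor, was 2187 ± 11.5 against 1667 ± 143, and Olfml3 was 1052 ± 29.3 against 795 ± 144. Aif1 (Iba1), a common microglial stain, was 147.4 ± 4.09 against 125.1 ± 9.38 and did not pass. Camera gave an adjusted p of 1.88e-08 for the list, and an adjusted p of 0.0972 with an estimated correlation.

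Complement transcripts formed the list that held in every set test. The 11 tested members fell to a mean of 0.65 times the control level, from −1.10 to −0.20 on the log2 scale, and 9 fell when adjusted over the list alone. The 3 chains of C1q, the initiator of the classical pathway, were C1qa at 4117 ± 517 in controls and 2651 ± 553 after AAV-NDNF, C1qb at 3193 ± 413 against 2075 ± 303, and C1qc at 2662 ± 366 against 1770 ± 326. C4b, the next component of that pathway, was 8585 ± 1220 against 5082 ± 1243, an uncertain value because its near-identical neighbour C4a can share reads. Camera gave an adjusted p of 5.17e-15 for the list, and an adjusted p of 0.0372 with an estimated correlation. The correlation estimated from the 6 libraries was −0.051 for complement, where it was 0.344 for disease-associated microglia. A value below 0 makes camera less strict than independent genes would, so that pass rests on an uncertain estimate. The complement list's adjusted p in fry, which asks whether the members move one way without reference to other genes, was 0.0076. Scores of the complement, disease-associated and homeostatic microglia lists did not overlap between the groups (each AAV-NDNF library below each control). Of the 36 lists tested, 5 showed no overlap, where chance gives 10%; the other 2, border macrophage and monocyte and fibroblast and extracellular matrix, did not pass camera.

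**Figure D2:**
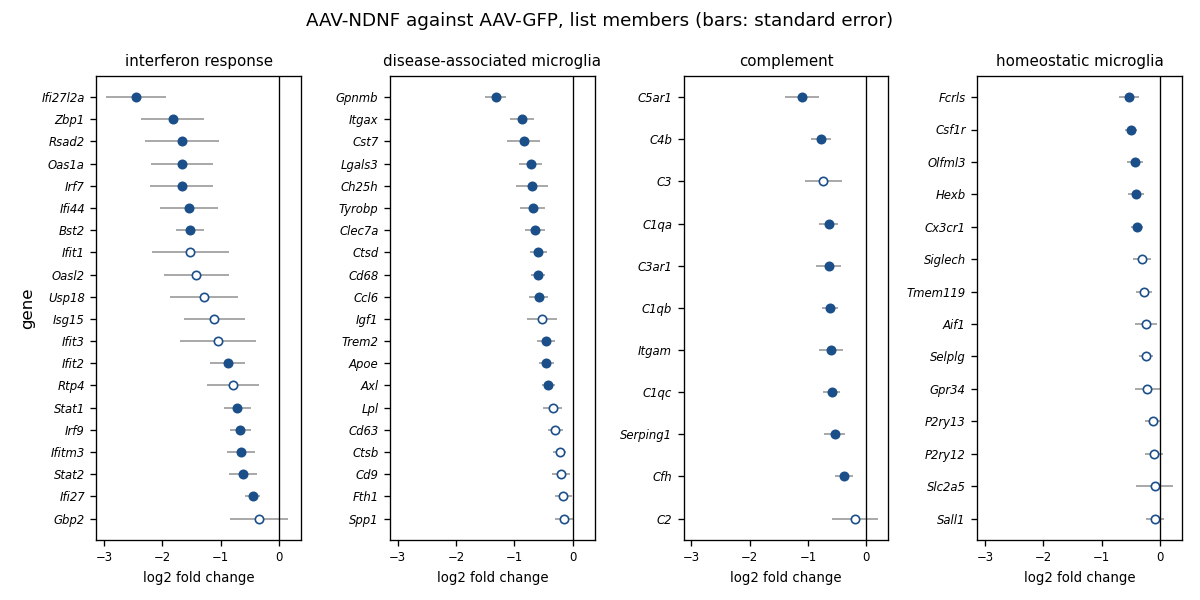
Log2 fold changes, AAV-NDNF against AAV-GFP (x axis), for the tested members of 4 gene lists (y axis, genes by size); bars are standard errors from limma, and filled points passed when adjusted over the list alone. All members lie below 0, from −2.46 for Ifi27l2a to values near 0 such as those of Sall1 and Slc2a5.

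Interferon-stimulated genes were the list with the largest mean difference, but 1 control library sat with the treated ones. The interferon response list fell to 0.437 times the control level (mean log2 fold change −1.19), all 20 members were below 0, and 13 fell when adjusted over the list alone. Ifi27l2a was 65.8 ± 16.4 in controls and 12.8 ± 7.91 after AAV-NDNF; its neighbour Ifi27l2b resembles it in sequence, so the value is uncertain. Irf9, the DNA-binding subunit of the type I interferon transcription complex, was 550.6 ± 91.0 against 347.9 ± 63.4. Ifi27 was 790.4 ± 72.3 against 577.9 ± 67.2. The list's score per library, relative to the control mean, was 0.50, −1.02 and 0.52 in controls 1 to 3 and −1.23, −0.88 and −1.47 after AAV-NDNF. Control replicate 2 thus lay within the AAV-NDNF range. Camera gave an adjusted p of 1.48e-22 for the list, and an adjusted p of 0.336 with an estimated correlation.

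Related immune lists moved in the same direction. The antigen presentation list fell to 0.634 times the control level, and 6 of its 14 members fell when adjusted over the list alone (camera adjusted p = 7.22e-09; adjusted p = 0.373 with an estimated correlation). The class I heavy chains H2-D1 and H2-K1 were 4179 ± 981 against 2536 ± 264 and 2225 ± 576 against 1353 ± 113; both share sequence with other class I genes and are uncertain for that reason. The antigen presentation score was 0.26, −0.61 and 0.34 in controls 1 to 3 and −0.06, −0.73 and −1.17 after AAV-NDNF, so control replicate 2 again lay within the AAV-NDNF range. Without AAV-NDNF replicate 3 the list's mean difference was −0.40 in place of −0.66. The T cell and cytotoxic cell list also fell (camera adjusted p = 0.0301; adjusted p = 0.373 with an estimated correlation). Its leading member was the chemokine Ccl5, at 44.6 ± 25.9 against 10.7 ± 2.98, and Cd8a was 23.6 ± 12.1 against 8.19 ± 10.6. Only 7 of the 14 genes of the T cell list were tested, and 1 passed when adjusted over the list alone. The median log2 fold change was −0.40, where the mean was −0.79. Trac, the T cell receptor alpha constant region, was 61.6 ± 11.2 against 52.6 ± 16.6. The T cell score of control replicate 2 (−0.44) also lay within the AAV-NDNF range (−1.13 to −0.22). That call was lost without AAV-GFP replicate 1 (adjusted p = 0.182) or AAV-NDNF replicate 3 (adjusted p = 0.125). The cytokine and NF-kB list passed camera narrowly (adjusted p = 0.035; adjusted p = 0.373 with an estimated correlation). None of its 17 members passed alone, and its leading members went both ways, with Tnf at 11.6 ± 2.39 against 4.59 ± 5.91 and Nos2 at 6.9 ± 10.2 against 14.2 ± 5.26. The call was lost without AAV-GFP replicate 1 (0.0732) or 3 (0.136) and without AAV-NDNF replicate 1 (0.161) or 3 (0.0986), all adjusted p from camera.

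Astrocyte genes of the reactive state were lower, whereas those of resting astrocytes did not pass. The reactive astrocyte list fell to 0.774 times the control level, with 15 of 16 members below 0 and 1, Aspg, past the threshold when adjusted over the list alone (417.3 ± 52.4 against 276 ± 11.5). Camera gave an adjusted p of 2.45e-09, and an adjusted p of 0.184 with an estimated correlation. The list's score was 0.06, 0.12 and −0.18 in controls and −0.38, −0.55 and −0.18 after AAV-NDNF. The groups thus overlapped, with AAV-GFP replicate 3 and AAV-NDNF replicate 3 level. Osmr, the oncostatin M receptor, was 541.2 ± 17.7 against 387.7 ± 73.3. Gfap, the intermediate filament of reactive astrocytes, was 108500 ± 17590 in controls and 84320 ± 8021 after AAV-NDNF (−0.36, SE 0.14), a difference that did not pass over all genes. For the homeostatic astrocyte list the mean difference was −0.07 (camera adjusted p = 0.168). Whether the reactive and homeostatic lists differed from each other was not tested. Slc1a2, the main glutamate transporter of astrocytes, was 35070 ± 4840 against 33270 ± 7088.

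**Figure D3:**
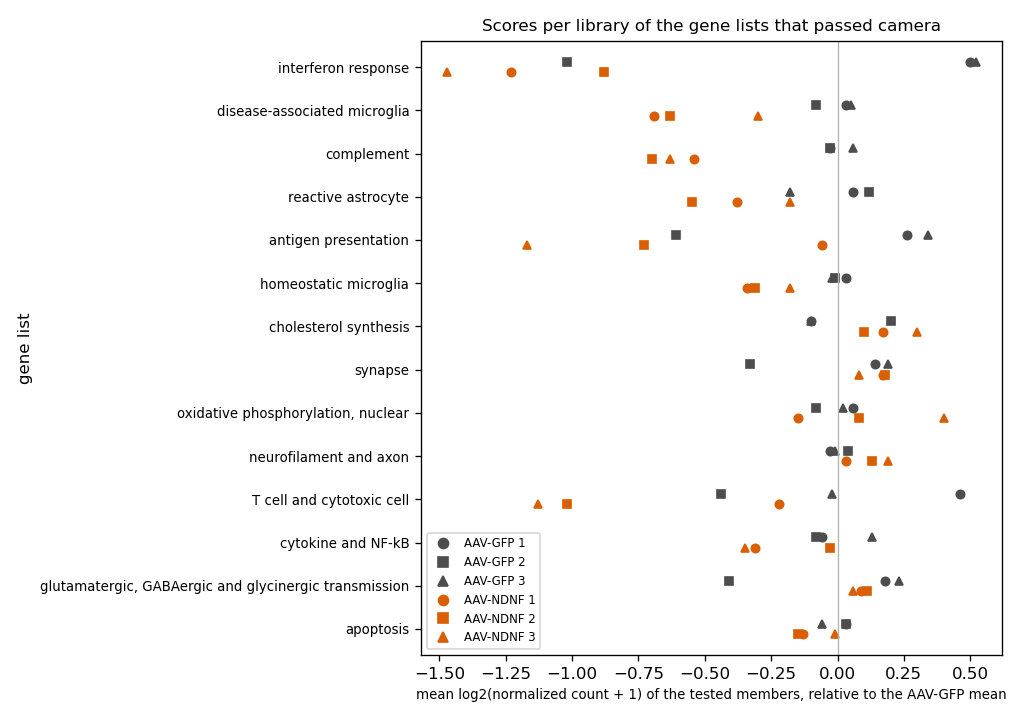
Score of each gene list that passed camera (y axis) in each library, as the mean log2(normalized count + 1) of its tested members relative to the AAV-GFP mean (x axis). The complement, disease-associated and homeostatic microglia lists separate the groups, whereas AAV-GFP 2 (−1.02) lies among the AAV-NDNF libraries for the interferon response.

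Neuronal and metabolic lists shifted by small amounts in the opposite direction. The cholesterol synthesis list rose to 1.14 times the control level, with 18 of 19 members above 0 (camera adjusted p = 2.49e-06; adjusted p = 0.373 with an estimated correlation). Its leading members were Msmo1, at 1382 ± 125 against 1819 ± 373, and Idi1, at 634 ± 116 against 805.6 ± 58.9. None passed when adjusted over the list alone. Without AAV-GFP replicate 2 the mean difference was 0.29 in place of 0.19, and without other single libraries it was 0.13 to 0.24. The cholesterol score of control replicate 2 (0.20) lay within the AAV-NDNF range (0.10 to 0.30). The neurofilament and axon list rose to 1.09 times the control level (camera adjusted p = 0.00934; adjusted p = 0.373 with an estimated correlation), with Nefh, the heavy neurofilament chain, at 20680 ± 2276 against 24170 ± 2081. That call was lost without AAV-GFP replicate 1 (adjusted p = 0.0588) or AAV-NDNF replicate 3 (adjusted p = 0.0892). The synapse list rose by a mean of 0.14 (camera adjusted p = 0.000329; adjusted p = 0.627 with an estimated correlation), Snap25 being 35910 ± 3623 against 42270 ± 5017. For glutamatergic, GABAergic and glycinergic transmission the rise was 0.09 (camera adjusted p = 0.0377; adjusted p = 0.648 with an estimated correlation), with the glycine receptor subunit Glrb at 4968 ± 193 against 6018 ± 867.

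Both of these neuronal calls were lost without AAV-GFP replicate 2, the library with the fewest dorsal horn transcripts. Its mean log2 level of dorsal horn neuron genes was −1.63 relative to the mean of the 6 libraries, where the others lay between −0.11 and 0.83. Without that library the synapse list differed by −0.02 (adjusted p = 0.98) and the transmission list by −0.12 (adjusted p = 0.752). With the dorsal horn score as a covariate both still passed camera, at 0.13 (adjusted p = 4.66e-05) and 0.07 (adjusted p = 0.0053). That score was balanced between the groups (means −0.04 and 0.04) and could hardly move a group difference. The covariate fit therefore does not offset the loss without AAV-GFP replicate 2. That omission, in turn, left controls with scores of 0.69 and 0.83, above all AAV-NDNF libraries (−0.11, −0.02 and 0.24). Dorsal horn content then differed by group, so neither fit decides whether these lists rose. The transmission call was also lost without AAV-NDNF replicate 1 (adjusted p = 0.13) or 2 (adjusted p = 0.142), and on the edgeR scale (0.04, adjusted p = 0.0524). The nuclear oxidative phosphorylation list rose by 0.11 (camera adjusted p = 0.0065; adjusted p = 0.729 with an estimated correlation), Ndufb9 being 216.7 ± 17.3 against 266.5 ± 54.7. It differed by −0.04 without AAV-NDNF replicate 3 and did not pass without AAV-GFP replicate 2 (adjusted p = 0.106). The apoptosis list was lower, with a mean log2 fold change of −0.095 (camera adjusted p = 0.0454; adjusted p = 0.373 with an estimated correlation). Its leading member was Cdkn1a (p21), a cell cycle inhibitor, at 781.3 ± 55.7 against 466.4 ± 74.05, whereas the pro-apoptotic Pmaip1 was 50.7 ± 11.6 against 79 ± 11.4. The apoptosis call was lost without AAV-GFP replicate 1 (0.0994) or 2 (0.182) and without AAV-NDNF replicate 1 (0.197) or 2 (0.179), as camera adjusted p.

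The remaining 22 of 36 lists did not pass camera, with adjusted p from 0.0863 to 0.962. For motor neuron genes the mean difference was −0.02 (adjusted p = 0.958), and Chat, the enzyme that makes acetylcholine, was 739.1 ± 119 in controls and 782.9 ± 93.9 after AAV-NDNF. For oligodendrocyte and myelin genes it was 0.03 (adjusted p = 0.588), Mbp (myelin basic protein) being 328200 ± 69670 against 307800 ± 19180. Border macrophage and monocyte genes differed by −0.55 (adjusted p = 0.0863), mitochondrially encoded genes by 0.13 (adjusted p = 0.0863) and unfolded protein response genes by −0.13 (adjusted p = 0.0937). Neuronal injury response genes differed by −0.06 (adjusted p = 0.392) and dorsal horn neuron genes by 0.07 (adjusted p = 0.415).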

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

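Limma replaced the planned edgeR test once the deposited unit was known. Alternatives chosen after seeing the data were edgeR on recovered reads, TMM, the pseudocounts, the dorsal horn covariate and the joint omission of AAV-GFP replicate 2 and AAV-NDNF replicate 3; the other alternatives were planned. Scaling by upper quartile or TMM, a filter of 1 CPM, pseudocounts of 0.5 and 5 and edgeR in both forms called 0 genes, as limma did. Higher and lower genes numbered 4 and 50 with DESeq2, 9 and 158 with limma-voom quality weights, 32 and 225 without both named libraries, and 50 and 145 at an unadjusted p under 0.05 with an absolute log2 fold change over 1. Without both named libraries the controls kept dorsal horn scores of 0.69 and 0.83, against −0.11 and −0.02 after AAV-NDNF. The gene and list counts of that setting therefore cannot separate treatment from dorsal horn content. Lower genes alone were called with no filter (3), the dorsal horn covariate (4) and the replicate block (6). Leaving out single libraries gave 0 to 1 higher and 0 to 43 lower genes. The causes were not tested.

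The DESeq2 rerun shared all 54 calls with the authors' deposited table, the quality weights shared 45 and omission of AAV-GFP replicate 2 shared 15. Replicate numbers did not pair the libraries: residual correlations of same-numbered libraries were −0.09, 0.05 and 0.08, and 2 of 6 libraries correlated best with their own number. The block ended the apoptosis call (adjusted p = 0.0605), as did the dorsal horn covariate (0.0539) and omission of both named libraries (0.055). Sex as a covariate was not run, since all libraries showed the male pattern.

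The Ndnf log2 fold change was 3.63 to 5.33 without single libraries, 4.83 with DESeq2 and 5.21 without both named libraries; the last 2 passed, as did omission of AAV-NDNF replicate 3, and the adjusted p ranged from 2.99e-13 to 0.9998.

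Of the 14 lists called, 1 passed with an estimated correlation and 1 with fry, the complement list in both. The other settings called 11 to 15 lists; without both named libraries 14 passed, of which 8 were among the original 14. Complement passed under all 18 alternatives, and the interferon, disease-associated and homeostatic microglia, reactive astrocyte, antigen presentation and cholesterol lists under 16. The filter of 1 CPM left the T cell list too few members to test.

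Several values changed sign. Sod1 was −0.16 with quality weights, −0.29 without both named libraries and −0.19 to 0.18 without single ones. Slc1a2 was 0.007, 0.178 and −0.243 to 0.067 in those settings. Mbp was 0.087 without both and −0.16 to 0.094 without single libraries. Ms4a4b was −1.26 to 0.011 without single libraries. The transmission list was −0.12 to 0.204 and the nuclear oxidative phosphorylation list −0.037 to 0.24 without single libraries, and without both named libraries they were −0.106 and −0.079. The synapse list was −0.023 to 0.238 without single libraries and 0.008 without both. The causes were not tested.

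Depth limits genes near 10 counts. With 3 libraries per group the simulated recovery of 0.5 log2 changes was 16%, with genes drawn independently, so real recovery can be lower.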

Other observations

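Tests chosen only after their result was seen are those of dorsal tissue, of microglial share, of control libraries 1 and 3, of reads moved to Hmga1b, of Glo1, of chromosome 17 in AAV-NDNF library 1, of the glucocorticoid response and of other splits by limma; genes in this part were named after their values were seen. Beyond the lists, the authors' deposited table holds further myeloid genes among its 54 calls. Ptprc (CD45) has a log2 fold change of −0.69, Laptm5, a lysosomal protein of blood-derived cells, −0.58, Itgb2, the shared chain of the leukocyte integrins, −0.58, and Grn (progranulin) −0.56. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, stands at −1.38 and the endosomal RNA sensor Tlr7 at −1.12. Interferon-inducible genes of the p200 family have Ifi204 at −1.76, Ifi207 at −1.78, Ifi209 at −2.00 and Ifi211 at −2.64; these similar, clustered genes can share reads.

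A few transcripts typical of other tissues were low or absent after AAV-NDNF, and were picked for that. Scgb1a1, an airway secretory protein, was 19.6, 38.1 and 22.4 normalized counts in AAV-GFP libraries and 1.7, 1.1 and 0 after AAV-NDNF. Igkc, the antibody kappa constant region, was 18.7, 33.2 and 16 against 0, 0 and 0, and Alb (albumin) 20.5, 45.9 and 9.6 against 0, 3.4 and 1.1. Carry-over was tested by the reads of other markers per read of the named gene in controls, with intervals that cover counting error only. The ratios were 1.57 (95% exact binomial interval 1.18 to 2.10) for lung, 1.22 (0.893 to 1.66) for liver and 24.1 (19.0 to 31.1) for antibody genes. The summed markers overlapped between the groups and left lung and liver undecided, at 33.2 to 48.1 against 10.1 to 37.2 for lung and 19.2 to 40.1 against 8.4 to 28.5 for liver. Within the lung sum the markers differed. Sftpc was higher in each control (14.3, 24.4 and 25.6) than in each AAV-NDNF library (0, 12.4 and 0). Ager overlapped, at 19.6, 7.8 and 22.4 against 5, 11.3 and 30.7. For antibody genes the controls did not exceed the AAV-NDNF libraries (422.2 to 622.7 against 452.5 to 623.3), the result set beforehand as counting against antibody-secreting cells. That limit was badly chosen, because Ighm made up most of the sum and varied from 366.5 to 594.8 in the 6 libraries, far more than the level of Igkc; without Ighm the sums were 23.2 to 55.7 against 20.3 to 28.5, which leaves this source undecided too.

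The lower level of the disease-associated microglia, homeostatic microglia and complement lists was weighed against dissection and cell number. Their joint mean difference was −0.48 (95% interval −0.68 to −0.28); a fit with the dorsal horn score as covariate, the test first set for this list and for interferon, was replaced because the score was balanced between the groups (means −0.04 and 0.04) and the fit could not decide. The dorsal horn scores of the AAV-NDNF libraries lay within the range of the controls. The highest AAV-NDNF joint score lay below the lowest control by a gap of 0.30 (SD of controls 0.04). A gap above 0 was fixed beforehand, since the 3 lists were already known not to overlap. The controls' joint scores were 0.01, −0.05 and 0.03, with dorsal horn scores of 0.69, −1.63 and 0.83 in the same order. Such a flat joint score argues against uneven dissection of dorsal tissue as the whole cause. An even loss of all microglia would lower both microglial lists alike if other cells added little to their members, which was not tested. The disease-associated list lay below the homeostatic one by a further −0.26 (95% interval −0.49 to −0.03). The smallest gap was in AAV-NDNF library 3 (−0.30 and −0.18). A loss mainly of disease-associated cells could give the same difference. The test thus argues only against an even loss, and only if other cells added little to either list. An effect of NDNF, of a differing response to each vector or protein, of handling or sequencing that differed by group, and of differences between animals were not separated by the design.

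The interferon response list gave −1.19 (95% interval −2.69 to 0.31) over library scores. With the dorsal horn score as covariate it gave −1.24 (−2.04 to −0.43). That narrower interval rests mainly on control 2, whose dorsal horn score (−1.63) lay far from the others. Control 2, the library poorest in dorsal horn transcripts, lay below the highest AAV-NDNF library (a gap of −0.15), so uneven dissection of dorsal tissue stays open for this list. A high interferon state in controls 1 and 3 alone fits the same value. That value restates the position of control 2 and is no separate test of such a state. The list may thus mark a state of individual mice, and a treatment effect on it stays open as well.

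Copies of the chromosome 17 genes Hmga1 and Glo1 had many reads in AAV-NDNF libraries 1 and 3 only. Hmga1b was 11.6, 0 and 7.5 in controls and 456.7, 1.1 and 1016.5 after AAV-NDNF, and Glo1-ps 1.8, 0 and 2.1 against 109.3, 9 and 204.8. The parent Hmga1 was lower in those 2 libraries (1483.6 and 1052.7, with 1760.3 to 2047.6 in the other 4), a log2 gap of 0.25 against an SD of 0.11, which argues against extra transcription of Hmga1b with an unchanged parent; Glo1 was not lower in both (1823.4 and 2326.6, with 1879.9 to 2107.1 in the other 4, a gap of −0.31), so the origin of the Glo1-ps reads stays open. The sum of Hmga1 and Hmga1b ran from 1761.4 to 2069.2, with a CV of 6.49% against 22.3% for Hmga1 alone, consistent with reads of 1 source assigned to either Hmga1 or Hmga1b. Genes that deviated were those over 1 log2 unit from the median of the other libraries, so smaller changes were not tested. A haplotype altering many genes of chromosome 17 between 20 and 45 Mb by that much is argued against in AAV-NDNF library 1. Genes there deviated with an odds ratio of 0.734 (0.347 to 1.38) against other genes. In library 3 such a haplotype cannot be told apart from other causes, since the interval is too wide (1.26, 0.824 to 1.87).

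Zbtb16 (−1.44), Plin4 (−1.70), Fkbp5 (−0.75) and Pdk4 (−0.76), which glucocorticoids induce, were lower after AAV-NDNF at an unadjusted p under 0.05 in limma. For the first 3 of these, control 2 (374.3, 399.7 and 568.8) lay nearer to the highest AAV-NDNF library (331.4, 377.6 and 547.7) than to controls 1 and 3. A lower glucocorticoid response was tested on 12 other responsive genes, of which 5 lay below 0; their mean was 0.07 (95% interval −0.55 to 0.68), which leaves it open. Dbp was higher, and a different time of day was tested with 7 clock genes in phase and 4 out of phase with it; their difference shifted by 0.09 (−0.23 to 0.42), which decides neither way.

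The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 818 genes at an unadjusted p under 0.05 in limma (reached in 4 splits, the real one included, highest other 2209). It gave 54 DESeq2 calls (2 splits, highest other 153), 14 lists past camera (4 splits, highest other 18) and 0 limma calls (10 splits, highest other 1). The highest values for genes at an unadjusted p, DESeq2 calls and lists all came from AAV-GFP 1, AAV-GFP 3 and AAV-NDNF 3 against the rest. Those 3 libraries had the most dorsal horn transcripts. That split also set apart AAV-NDNF 3 and AAV-GFP 2, the ends of the first principal component. Whether dorsal horn content underlies its high counts was not tested. In the real split, with the dorsal horn score as a covariate, limma called 0 higher and 4 lower genes. The camera p of the complement list was 4.31e-16 in the real split and at least 0.00194 in the others, and that of disease-associated microglia 1.69e-23 and at least 2.26e-10. For the interferon list another split gave a smaller p (3.79e-36 against 4.12e-24).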
